A study of Mus musculus with 4 samples.

How the data were processed

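Single-cell RNA libraries were made from cells of mouse cortex that had been sorted as negative for CD45, the pan-leukocyte surface protein, and for the dead-cell dye DAPI. Cortices were dissociated with enzymes, depleted of myelin and stained before the sort, per the labels' protocols. The libraries used droplet capture with the GEM-X 3' v4 chemistry of 10x Genomics, in which a droplet is meant to hold a single bead whose barcode marks the transcripts of the cell inside it. The protocol set a target of 20000 cells per sample. Cell Ranger and Seurat, with the GRCm39 genome build, are named in the submitters' processing notes, without versions. The annotation release and the rule for calling cells are not given in the sources used here.

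For each library, the tables analysed here were a list of the cell barcodes that the authors deposited as filtered, and a list of the genes that were counted. Neither table holds a measurement per gene. UMI counts per cell were not analysed here, so no gene's level, no cell type, no depth per cell and no doublet rate is reported. The planned tests of gene changes in endothelial-like and other cell classes, of shares of cell classes and of gene lists all need such counts and were not run. The rule fixed for naming genes (the 12 largest rises and 12 largest falls per cell class among genes past the test's threshold and separating the genotypes in both libraries, plus Maf and Cldn5) therefore named no gene for its value.

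The 4 libraries were grouped by genotype from their titles, 2 from Maf-flox mice and 2 from Maf-flox mice with Crybb1-Cre. All carry batch 1 in the labels. The labels do not say whether libraries of a genotype came from separate animals. The p-value for the genotypes' barcode numbers therefore measures the spread between these libraries, which may be technical. The p-values for barcode sequences take single barcodes as units and do not measure that spread. The genotypes' barcode numbers were compared with a two-sided exact permutation test on the difference of means, which with 2 libraries against 2 has 3 distinct splits and cannot give a p under 0.333.

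Barcodes were compared as sequences without the library suffix. The number shared by each pair of libraries was set against a common rate times the product of the 2 barcode numbers. Deviation over the 6 pairs was measured by a chi-square with a Monte Carlo p from 100000 multinomial draws, and each count has a 95% exact Poisson interval. The procedure was tested on simulated libraries of the same sizes. With no barcode carried over, 6.5% of 200 simulations were called at the 0.05 threshold. With 40 barcodes carried from the simulated Maf-flox replicate 1 to Maf-flox replicate 2, 57% were called, and with 60 carried 93.5% were called. Carry-over between other pairs was not simulated. Intervals cover counting error only.

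Gene types were looked up by identifier in the GENCODE M21 primary assembly annotation, which lacked 1684 of the 33696 identifiers. Symbols were compared with a separate table of mouse gene names, which held 31961 of them (94.9%), of which 29374 carried the same symbol. The M21 release annotates GRCm38, another build than the one in the processing notes, so it was used for gene types and no coordinates are given. Computation used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1 and Matplotlib 3.10.9. The designs, alternatives and gene lists were fixed before the data were examined. The alternatives run were the ratio of geometric means, the replicate number as a block, a barcode match with 1 mismatched base, and leaving out each library in turn.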

Results

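The series asks how perivascular macrophages of the brain affect endothelial cells through cMAF, the transcription factor encoded by Maf. Cells were taken from mice with a floxed Maf allele, either without Cre or with Cre under Crybb1, a crystallin gene that is also expressed in microglia and brain macrophages. CD45-negative cells were sorted for sequencing, a gate that is set to leave out leukocytes, macrophages included. Each genotype was represented by 2 libraries, and the 4 libraries together listed 85077 cell barcodes. UMI counts were not analysed here, and the depth per cell is unknown.

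The genotypes were first compared for the number of cell barcodes kept. The Maf-flox libraries listed 23212 barcodes in replicate 1 and 22924 in replicate 2, a mean of 23068 ± 204 (SD, n = 2). The Maf-flox Crybb1-Cre libraries listed 23794 in replicate 1 and 15147 in replicate 2, a mean of 19471 ± 6114 (SD, n = 2). The Crybb1-Cre mean was 0.844 times the Maf-flox mean. This difference was smaller than the spread within the Crybb1-Cre genotype, whose libraries lay 8647 barcodes apart, against 288 for the Maf-flox libraries. The two-sided exact permutation test gave p = 1, where the smallest p that 2 libraries against 2 can give is 0.333. The direction rested on Crybb1-Cre replicate 2, without which the ratio was 1.03. A barcode number is a yield that follows the number of cells loaded and recovered, and it measures neither the number of cells in the cortex nor their state.

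**Figure D1:**
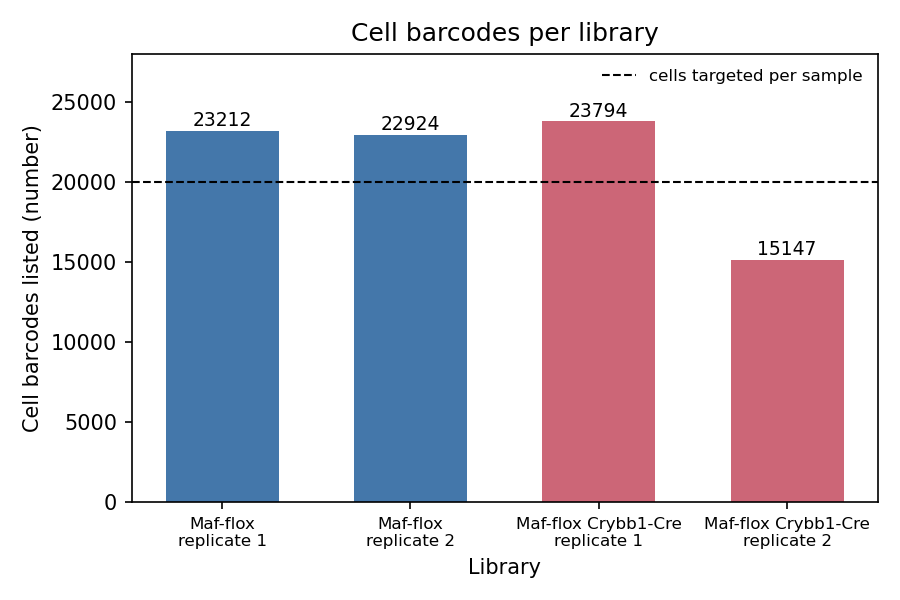
Cell barcodes listed in each of the 4 libraries (bars, number on a linear axis from 0), coloured by genotype, with the 20000 cells targeted per sample as a dashed line. Crybb1-Cre replicate 2, at 15147, lies below the line, and the other 3 libraries, at 22924 to 23794, lie above it.

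Set against the target of 20000 cells, 3 libraries exceeded it and 1 fell short. Maf-flox replicate 1 reached 116% of the target and Maf-flox replicate 2 reached 115%. Crybb1-Cre replicate 1 reached 119% and Crybb1-Cre replicate 2 reached 75.7%. The last library held 65.0% of the mean of the other 3.

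The libraries were next compared for the cell barcodes they had in common, which bears on barcodes carried between libraries and not on whether libraries came from separate animals. The 6 pairs of libraries shared between 84 and 159 barcodes, and 727 in sum. Maf-flox replicate 2 and Crybb1-Cre replicate 1 shared the most, 159 barcodes against 147 expected from the product of their sizes. Maf-flox replicate 2 and Crybb1-Cre replicate 2 shared the fewest, 84 against 93.9 expected. Across the pairs the ratio of observed to expected ran from 0.895 to 1.08, and in 6 of 6 pairs the expected number lay inside the 95% Poisson interval of the count. The deviation from the common rate was not larger than sampling noise (p = 0.661 by the Monte Carlo test of the chi-square). The pair of Maf-flox libraries shared 149 barcodes against 144 expected, and the pair of Crybb1-Cre libraries shared 90 against 97.4.

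**Figure D2:**
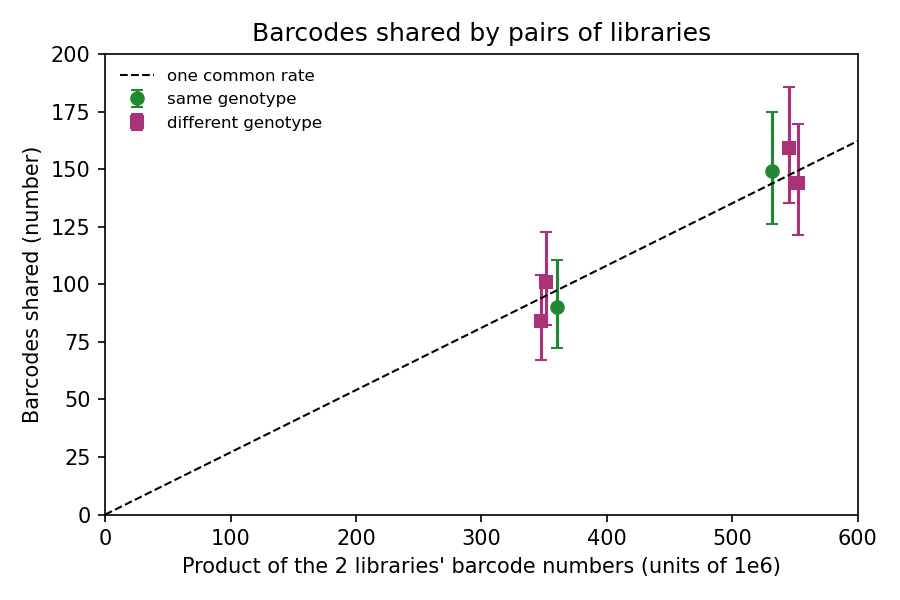
Barcodes shared by each of the 6 pairs of libraries (vertical axis, number) against the product of the libraries' barcode numbers (horizontal axis, in units of 1e6), with 95% exact Poisson intervals as bars, circles for pairs of one genotype and squares for pairs of different genotypes. The dashed line is one common rate, and it passes through the intervals of all 6 pairs, whose counts run from 84 to 159.

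The genes that could be measured were the same in all libraries. The 4 gene lists agreed in identifier, symbol and order over 33696 genes. Maf (ENSMUSG00000055435), the floxed gene, and Crybb1 (ENSMUSG00000029343), the gene whose promoter names the Cre line, each stood on 1 line. Each of the 33696 identifiers was an Ensembl mouse gene, so the list had no separate entry for the Cre transgene. In the GENCODE M21 annotation, 21409 of these genes (63.5%) are protein-coding, 5585 are lincRNA genes and 2952 are antisense genes, while 1684 identifiers were not found in that annotation. The list also held 13 genes with the mitochondrial prefix.

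The gene groups fixed for this study, vascular and other, were fully represented in the counted annotation. This shows only that their genes could be counted, as no level was read for any of them. The 13 barrier and tight junction genes were all listed, among them Cldn5, which encodes the main claudin of brain endothelium, and Mfsd2a, a lipid transporter of the blood-brain barrier. The 5 transcytosis genes, including Plvap, which encodes a protein of fenestral diaphragms, and Cav1, which encodes a caveolar coat protein, were listed as well. The same held for the 10 Wnt target genes such as Axin2 and Lef1, the 10 arterial genes such as Bmx and Gja5, the 8 venous genes such as Nr2f2 and Slc38a5, and the 5 capillary genes such as Rgcc. The 9 interferon genes, the 7 MHC genes, the 10 genes of angiogenesis and tip cells, the 6 genes of nitric oxide and vascular tone and the 10 genes of the dissociation response were also complete. So were the 9 genes chosen to reveal other cells that pass the gate, macrophage and erythroid genes such as Csf1r and Hba-a1. In the 11 lists of cell type markers, from endothelial cells (Pecam1, Cdh5) and pericytes (Kcnj8, Abcc9) to smooth muscle (Acta2, Myh11), fibroblasts (Dcn, Col1a1), astrocytes (Aqp4), oligodendrocytes (Mbp) and microglia (P2ry12), no gene was missing. Over all 23 lists, 145 of 145 distinct genes were present, each under a symbol used on a single line. Elsewhere in the annotation, 26 symbols stood on more than 1 line, covering 52 genes that a table joined by symbol would merge.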

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

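The ratio of barcode numbers between Crybb1-Cre and Maf-flox libraries, 0.844, was 0.823 with geometric means and 0.843 with the replicate number as a block (within number 1 the Crybb1-Cre library held 582 more barcodes, and within number 2 the difference was -7777). Whether the numbers pair the libraries could not be checked with 2 of them and no expression values. Leaving out each library in turn gave ratios from 0.657 to 1.03. The highest value, a reversed direction, came from leaving out Crybb1-Cre replicate 2, and the lowest from leaving out Crybb1-Cre replicate 1. None of these settings could have passed the threshold of 0.05 with so few libraries. The Monte Carlo p for shared barcodes, 0.661, ran from 0.296 to 0.622 when each library was left out. Allowing 1 mismatched base changed nothing, because no 2 barcodes lay 1 base apart. A further 14 alternatives set in advance for gene changes and cell classes were not run, since they need UMI counts, and no depth per cell was available to set their precision.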

Other observations

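The tests in this part were chosen after the data were seen, except the test of shared barcodes over the pairs, which was set before the data were examined, and those on barcodes 1 base apart, on repeated ends in exactly 2 libraries and on repeated ends in 1 library, which were set out before their results were seen. The rule for judging carry-over from the shared barcodes was written after the data were seen.

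Crybb1-Cre replicate 2 listed 15147 barcodes, fewer than the other 3 libraries. A table cut short would lack barcodes from the end of the alphabet, because the tables are sorted. Of its barcodes, 9.88% lay in the range that holds the last 10% of the sorted barcodes of the other libraries (95% exact binomial interval 9.41% to 10.4%), which argues against that. An effect of genotype on yield and a lower number of cells loaded or recovered cannot be told apart here: the highest Crybb1-Cre library held 870 barcodes more than the lowest Maf-flox library, and 2 libraries per genotype do not exclude a smaller effect.

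The barcodes themselves show how the list they were drawn from is built. Their first 8 bases took 3840 forms and their last 8 bases 3839 forms, which joined only within 4 classes. Joining every 5' part with every 3' part of its class gives a list of 3685440 barcodes. The number fitted from the overlaps between libraries alone was 3698902 (95% Poisson limits 3439526 and 3983222). With the list from the joined parts, 730 shared barcodes were expected over the 6 pairs and 727 were seen (95% Poisson interval 675 to 782). This argues against carried cell barcodes in numbers that would raise the expected sum above 782. The p of 0.661 bears only on carry-over that is uneven between pairs, because the common rate was fitted to the same counts. A smaller carry-over stays open, whether spread over the pairs or of about 40 barcodes in one pair. Between the Maf-flox libraries, the only pair simulated, 57% of simulations with 40 barcodes carried were called. Carried reads too few for their barcode to be listed as a cell were not tested and stay open as well. No barcodes within a library lay 1 base apart (0 pairs), but none did between libraries either, so this says nothing about cells counted under a misread barcode.

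A few barcodes came back in more libraries than random draws give. While 691 barcodes stood in exactly 2 libraries against a simulated mean of 719, 8 stood in 3 libraries and 2 in all 4. For 3 or 4 libraries, 10 barcodes were seen against a mean of 2.75 and a highest value of 9 in 2000 simulations (one-sided p = 0.0005 by this Monte Carlo approximation of the exact test, the smallest it can give). The 2 in all 4 libraries were CTGTGGGTCTATGTGG and TGGTGGTTCTTGATGG. In 8 of the 10, including both of these, the last 6 bases repeated the first 6 with at most 1 difference, and all 8 belonged to the same joining class, which also held 140 of the 444 barcodes with repeated ends found in 1 library. That is 80% (95% exact binomial interval 44.4% to 97.5%), against 0.531% of the barcodes found in 1 library (444 of 83663).

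Reads carried between libraries would bring ordinary barcodes, few of which have repeated ends. The repeat was noticed on these same 10 sequences, however, so the share of 80% is no independent test and does not decide on carry-over. That barcodes of this form may arise in the chemistry and not on single beads is a hypothesis. Among barcodes in exactly 2 libraries 5 of 691 had repeated ends, an odds ratio of 1.37 against barcodes in 1 library (95% interval 0.440 to 3.23, Fisher's exact test, two-sided p = 0.425). This leaves open whether barcodes with repeated ends stand in exactly 2 libraries more often than others, and it does not bear on 3 or 4 libraries. Among barcodes in 1 library, 444 had repeated ends. This was 1.02 times the mean of 435 over 1000 shufflings of the 3' parts within their classes (one-sided permutation p = 0.338). The shufflings ran from 362 to 507, so no general excess was seen, but a small one is not excluded. The classes were counted together. An excess confined to the class of the repeats among the 10 barcodes, which held 140 of the 444, was therefore not tested. Whether the 10 barcodes hold cells was not tested, as it needs their UMI counts, and no biological explanation was tested.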
